A study of Mus musculus with 6 samples.

How the data were processed

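Gene expression was measured in whole dorsal skin of mice on day 2, in 3 control samples and 3 samples given DPCP (diphenylcyclopropenone, a contact sensitizer that provokes a delayed allergic reaction in skin), per the labels. Per the labels' protocols, tissue pieces were kept in RNAlater, RNA was isolated with TRIzol, and polyadenylated RNA was made into libraries with a strand-preserving Illumina kit and read in pairs on a NovaSeq instrument. The labels do not say what the control skin received, nor whether the 3 samples of a group came from separate animals. The p-values therefore measure the spread between these samples, which may in part be technical.

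The deposited values were raw read counts per gene, made with featureCounts 1.6.2 from the Ensembl GRCm38 annotation, release 102, per the file headers. The command in the file headers set no option for strand, read pairs, reads with several alignments or reads over several genes, so each mate was counted on its own, on either strand, and ambiguous reads were not counted. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.2.1, StringTie 2.2.1, DESeq2 1.34.0 and the genome build mm10. This counting affects the measurements in 3 ways. Reads of near-identical genes (the Krt6a and Krt6b pair, the Sprr2 genes, the Skint genes, the hemoglobin alpha genes) are lost wherever they align to several places, so levels of such genes are uncertain. Antisense transcripts cannot be told from sense ones. Reads in exons shared by 2 genes are dropped, and 5988 of the 18259 genes tested (32.8%) shared at least 1 exon base with another gene. Among the genes named in the results, the levels of Krt6b, Krt6a, Krt10, Krt32, Adh6b, Il1b, Csf1r, Lef1, Il4ra, Cd3e, Ccl27a, Nlrc5, Ereg, Wnt7b, Axin2, Rspo3, Hgf, Spp1, Bmp4, Mb, Tnc and Selp are uncertain for this reason.

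The table held 55487 genes, of which 55141 identifiers were matched to a symbol in the GENCODE M21 annotation of the same build. That annotation also gave each gene's biotype and GC content, and coordinates are those of the deposited table on GRCm38. Library totals were 28346992 to 38846787 counts, with mitochondrial genes taking 3.96% to 4.07% of the counts in control and 3.41% to 3.49% in DPCP libraries. A count of 0 in a library allowed a level of up to 0.0772 to 0.106 CPM (3 counts of the total), which covers counting error only. That bound takes reads as independent, though mates were counted separately. Within groups the log2 CPM of library pairs correlated at 0.985 to 0.987 across genes, and between groups at 0.926 to 0.946. Every pair differed by more than counting noise (chi-square per gene of at least 19.9), so no library was counted as a copy of another.

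Differential expression was tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM factors (0.942 to 1.04) and filterByExpr at its defaults. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes are the unshrunken log2 fold change divided by the square root of the F statistic. CPM values are given as mean and SD of 3 libraries. The 35 gene lists covered immune cells, inflammation, keratinocytes, the hair follicle and the other tissues of skin, and held 501 tested genes, 6 of them in more than 1 list. They were tested with camera of limma 3.58.1 (2-sided, preset correlation of 0.01, log2 CPM, Benjamini-Hochberg over the lists). Older symbols in the lists were matched through the RefSeq gene table.

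The lists, the test and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes with the largest increase and the 10 with the largest decrease among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups in CPM, leaving out predicted genes and pseudogenes. It adds 14 genes named in advance, and from each list up to 3 members with the smallest p in the list's main direction and 1 called in the other. A list without a called member gives the 2 with the smallest p, as values.

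On simulated counts for this comparison (10 draws of 17903 to 17943 genes with 200 changed genes each), the procedure recovered 33.8% of the genes changed 1.5-fold, 83.2% of those changed 2-fold and 98.2% of those changed 4-fold. Of its calls, 8.34% were false, a larger share than the threshold on the adjusted p aims at. Only 200 genes were changed in each draw, whereas 46.1% of the tested genes were called in the real comparison. Recovery and the false share depend on how many genes change, so these percentages do not carry over to the real calls. A shifted list was called in each of the 10 draws, and no other list was. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.93 (red blood cell genes). The draws therefore do not show how often camera calls a list falsely in these data. Alternatives were RLE and upper-quartile factors, library totals alone, DESeq2 1.42.0, limma-voom, other count filters, other thresholds, a replicate block, each library left out in turn, muscle, adipocyte and red cell genes left out, and 3 other list tests. Protein-coding genes alone, the omission of a ribosomal RNA gene and genes sharing no exon base were added after the data were seen. Tests on FPKM or TPM values were planned for tables that hold them and were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.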

Results

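The data were gene counts from 6 libraries of whole dorsal mouse skin taken on day 2, 3 from control skin and 3 from skin given the contact sensitizer DPCP. The 3 control libraries held 28346992, 28855768 and 33468828 counts and the 3 DPCP libraries 34708959, 38846787 and 31609336. The study's title concerns macrophages in hair regeneration induced by contact hypersensitivity, and the comparison asks how DPCP skin differed from control skin in gene expression at this early time.

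At day 2 the lists of neutrophil, chemokine, epidermal stress and cell cycle genes were higher in DPCP skin, while those of hair follicle growth signalling, lipid synthesis and skeletal muscle genes were lower, by camera with a preset correlation of 0.01. None of these list calls held with an estimated correlation (smallest adjusted p = 0.58 with an estimated correlation), and other splits of the 6 libraries called up to 25 lists against 16 in the real one. Those splits mixed the groups unevenly, so part of the DPCP difference stayed in them and their counts set no chance level. Saa3, an acute-phase serum amyloid gene, went from 0.220 ± 0.129 CPM (SD, n = 3) in control to 484 ± 157 CPM (SD, n = 3) in DPCP skin, and the neutrophil-attracting chemokine Cxcl2 from 0.253 ± 0.161 to 122 ± 83.3 CPM. Keratin Krt6b, made by stressed keratinocytes, rose from 21.4 ± 10.3 to 5280 ± 542 CPM. The largest decreases under the naming rule were those of Mt4, a metallothionein of differentiating squamous epithelium (52.6 ± 12.03 to 1.68 ± 0.524 CPM), and Serpinb6e (110 ± 36.5 to 5.74 ± 2.50 CPM). Wnt10b, a Wnt ligand of the hair follicle, fell from 12.4 ± 1.59 to 0.939 ± 0.0879 CPM.

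Of 18259 genes tested with edgeR's quasi-likelihood test, 4163 were higher and 4254 lower in DPCP skin at a Benjamini-Hochberg adjusted p under 0.05, and 9842 were not called. At least 4-fold differences were found for 516 of the higher and 385 of the lower genes. The median log2 fold change of all tested genes was −0.01, and the first principal component of log2 CPM, with 77.1% of the variance, parted the groups. On it DPCP replicate 1 lay at 49.2, nearer to the control libraries than the other 2 DPCP libraries at 73.8 and 71.9. DPCP replicate 2 gave 2.46% of its counts to CT010467.1, a gene annotated as ribosomal RNA, against 0.420% and 0.489% in the other DPCP libraries and 0.167% to 0.285% in control.

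The 10 genes with the largest increases under the naming rule were Saa3, Prl2c3, Cxcl5, Cxcl2, Cdhr1, Krt6b, Il24, Trem1, Igfl3 and Cxcl3. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) had a log2 fold change of 11.04 ± 0.39 (SE) at an edgeR adjusted p of 1.86e-06. The neutrophil chemokine genes Cxcl5, Cxcl2 and Cxcl3, all on chromosome 5, rose by log2 fold changes of 9.12 ± 0.84, 8.87 ± 0.71 and 7.50 ± 0.71 (SE). Without DPCP replicate 2 those of Cxcl2 and Cxcl3 were 8.17 and 6.74, and without control replicate 3 that of Cxcl5 was 9.77. Trem1, a receptor gene of neutrophils and monocytes, rose by 7.88 ± 0.95, and by 6.87 without DPCP replicate 2. Igfl3 rose by 7.65 ± 0.42. Il24, a cytokine of the IL-20 family, rose by 7.94 ± 0.43 (SE) from 12 counts over the control group to 3322, and by 9.76 without control replicate 3. Cdhr1 rested on 4 control counts, and its log2 fold change of 8.79 was 8.19 without control replicate 3. Prl2c3 had 1 count in the control libraries together and 1976 in the DPCP libraries, a ratio of library shares of 1704 with a counting interval of 305 to 67325 (95%, exact). That control count lay in control replicate 2, and near-identical Prl2c copies make the level of this gene uncertain. The interval covers counting error alone and takes reads as independent. Mates of a pair were counted separately, so it is likely too narrow. Prl2c3 was at 4.04, 40.07 and 11.95 CPM in the DPCP libraries, with a log2 fold change of 10.32 ± 1.47 (SE, edgeR adjusted p = 0.000613).

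Among the 10 largest decreases, Mt4 (ENSMUSG00000031757, chromosome 8, 94137197 to 94139031) had a log2 fold change of −4.96 ± 0.25 (SE) at an edgeR adjusted p of 5.88e-06. The log2 fold changes of Mylk4, a myosin light chain kinase gene, the potassium channel gene Kcnj16 and Il1f10, an interleukin 1 family member, were −4.14 ± 0.14, −4.05 ± 0.29 and −3.86 ± 0.27 (SE). Those of Skint5 and Skint7, of a family expressed in keratinocytes, were −3.94 ± 0.31 and −3.58 ± 0.18, and those of Slurp2 and Adh6b −3.72 ± 0.37 and −3.65 ± 0.40.

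**Figure D1:**
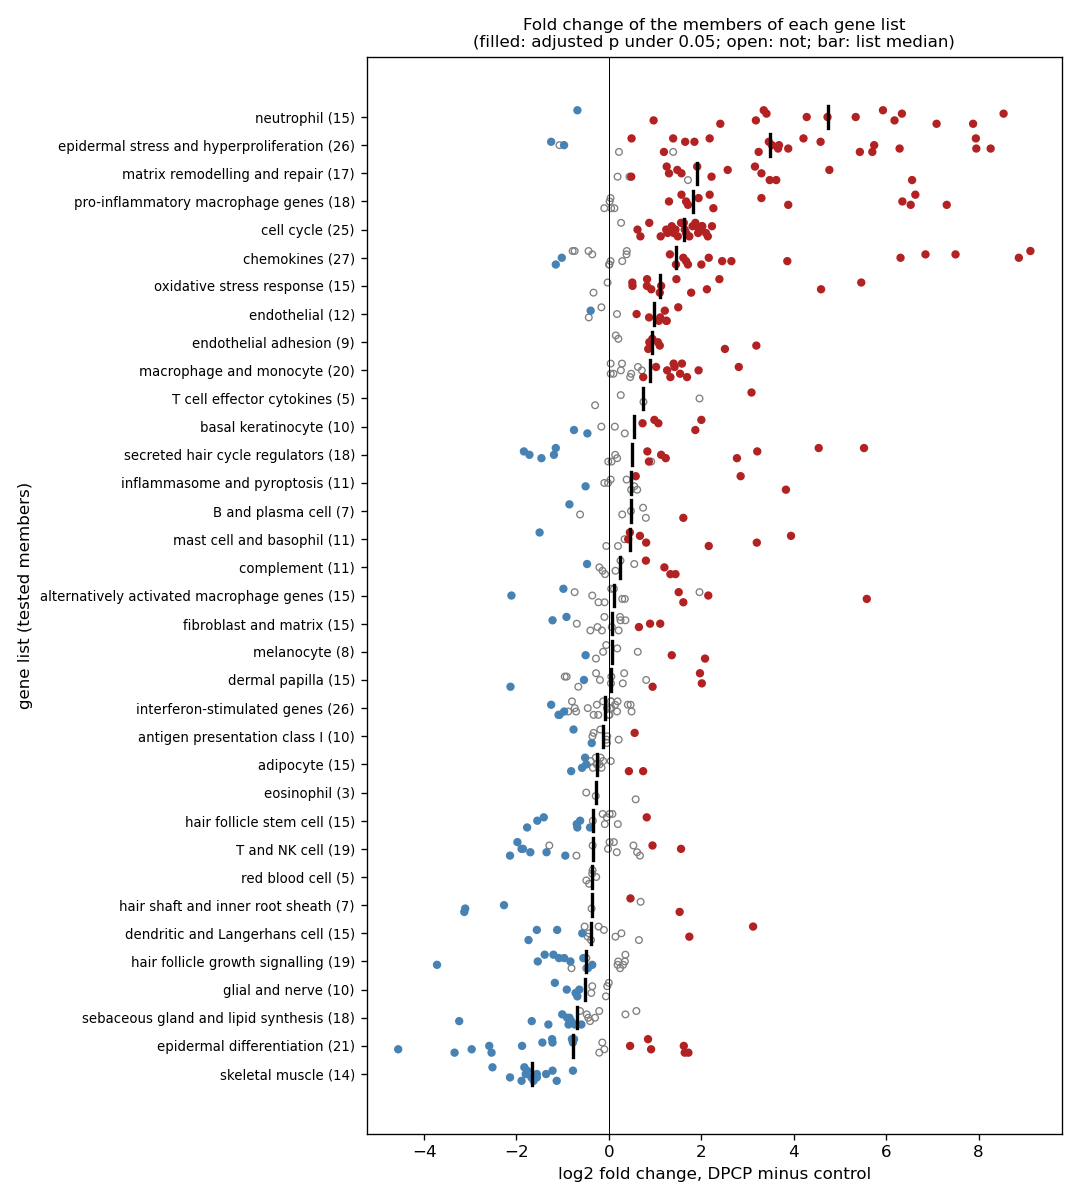
Log2 fold change (DPCP minus control, x axis) of every tested member of the 35 gene lists (y axis, number tested in parentheses), filled where the edgeR adjusted p was under 0.05 (red higher, blue lower) and open where it was not, with a bar at each list's median. Neutrophil genes had the highest median (4.73) and skeletal muscle genes the lowest (−1.66).

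Macrophage genes differed by member. Of 20 macrophage and monocyte genes, 11 rose, none fell and 9 were not called (12 and 0 adjusted over the list alone), and the list was higher at a camera adjusted p of 0.0011. Its call was lost with an estimated correlation (adjusted p = 0.72 with an estimated correlation) and was not reached by fry (adjusted p = 0.063). Cd68, a lysosomal protein of macrophages, rose from 68.1 ± 22.9 to 197 ± 41.4 CPM (SD, n = 3; log2 fold change 1.54 ± 0.25, SE), the mannose receptor gene Mrc1 by 1.40 ± 0.29 and the scavenger receptor gene Msr1 by 1.94 ± 0.25 on the log2 scale. Adgre1, which encodes F4/80, was at 99.1 ± 26.7 and 136 ± 29.0 CPM, and Csf1r, the receptor for colony stimulating factor 1, at 351 ± 79.6 and 420 ± 84.0 CPM, neither called (edgeR adjusted p = 0.117 and 0.306). Without a count filter Adgre1 was called higher (adjusted p = 0.0233). Exons of Csf1r overlap those of Hmgxb3 on the other strand.

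Of 18 pro-inflammatory macrophage genes, 13 rose and none fell, in both the count over all genes and that adjusted over the list alone, with a median log2 fold change of 1.82 and a camera adjusted p of 0.00012 (adjusted p = 0.58 with an estimated correlation). Il1b rose by 6.53 ± 0.60 on the log2 scale (SE; 2.32 ± 1.06 to 213 ± 151 CPM, SD, n = 3) and by 5.79 without DPCP replicate 2, and an antisense gene, Il1bos, shares its exons. Il6 rose by 6.63 ± 0.67, or by 5.96 without DPCP replicate 2, Socs3 by 2.18 ± 0.20 and Tnf by 1.94 ± 0.29. Nos2, the inducible nitric oxide synthase gene, was at 1.31 ± 0.502 and 1.343 ± 0.425 CPM (edgeR adjusted p = 0.923). Counts from whole skin do not tell which cells made the RNA of this list or of the next. Of 15 alternatively activated macrophage genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.38). Its adjusted p was 0.0226 with DESeq2 statistics and ranged up to 0.811 over the alternatives. Chil3 rose by 5.58 ± 0.27 and Il4ra by 2.15 ± 0.24 on the log2 scale, while Arg1 was at 39.5 ± 7.68 and 36.9 ± 18.7 CPM (log2 fold change −0.09 ± 0.31, adjusted p = 0.824) and was called lower only without DPCP replicate 2 (−0.60, adjusted p = 0.0292).

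Neutrophil genes were the list with the highest median. Of 18 members, Ly6g, Ngp and Ltf had too few counts to be tested. Of the other 15, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 4.73 and a camera adjusted p of 1.8e-06 (adjusted p = 0.58 with an estimated correlation). S100a8 and S100a9, calcium-binding proteins of neutrophils and stressed keratinocytes, rose by 7.09 ± 0.47 and 6.18 ± 0.51 and Lcn2 by 5.34 ± 0.34 on the log2 scale (SE). Il1r2, the decoy receptor gene for interleukin 1, fell by 0.68 ± 0.21. It was not called without control replicate 1, DPCP replicate 1 or DPCP replicate 3 (log2 fold changes of −0.57, −0.56 and −0.53).

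Of 27 chemokine genes, 15 rose and 2 fell (15 and 3 adjusted over the list alone), with a camera adjusted p of 0.0023 (adjusted p = 0.58 with an estimated correlation). Ccl2, which attracts monocytes, rose from 7.03 ± 2.44 to 38.3 ± 15.8 CPM (SD, n = 3) and Ccl3 by a log2 fold change of 6.31 ± 0.53 (5.68 without DPCP replicate 2), while the skin chemokine Ccl27a fell by 1.15 ± 0.23. Of 9 endothelial adhesion genes, 7 rose and none fell (7 and 0 adjusted over the list alone), with a camera adjusted p of 0.0027 (adjusted p = 0.65 with an estimated correlation). The E-selectin gene Sele rose by 2.51 ± 0.19 and the P-selectin gene Selp by 3.19 ± 0.31 on the log2 scale. Of 12 endothelial genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them Pecam1 by 1.25 ± 0.12, and the camera adjusted p was 0.012 (adjusted p = 0.58 with an estimated correlation).

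Of 11 mast cell and basophil genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.029 (adjusted p = 0.58 with an estimated correlation). The adjusted p was 0.0603 with DESeq2 statistics and 0.148 with at least 1 CPM in a whole group, in a range of 0.00563 to 0.576 over the alternatives. Fcer1a, a chain of the IgE receptor, rose by 3.20 ± 0.38 and the mast cell protease gene Cpa3 by 0.81 ± 0.15 on the log2 scale (SE), while the mast cell receptor gene Mrgprb2 fell from 11.8 ± 0.205 to 4.16 ± 1.07 CPM (SD, n = 3). Inflammasome genes rose in 3 of 11 cases and fell in 1 (3 and 1 adjusted over the list alone; camera adjusted p = 0.21), led by Nlrp3 at 3.83 ± 0.57, which was 2.87 without DPCP replicate 2. Of 11 complement genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.38).

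Of 19 T and NK cell genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.36). Cd3e fell from 6.86 ± 0.763 to 1.55 ± 0.625 CPM (SD, n = 3; log2 fold change −2.14 ± 0.29, SE). The log2 fold changes of Cd3g and the perforin gene Prf1 were −1.86 ± 0.20 and −1.98 ± 0.27, whereas Cd4 rose by 0.94 ± 0.25. Only 5 of the 16 T cell effector cytokine genes had enough counts to be tested, and Ifng, Il17a and Il22 were among those that had not. Of the 5, 1 rose, Tnfsf14 (3.08 ± 0.42), both over all genes and adjusted over the list alone (camera adjusted p = 0.39). Of 26 interferon-stimulated genes, none rose and 4 fell, and no member passed when adjusted over the list alone (camera adjusted p = 0.50). The list was called lower without control replicate 3 (adjusted p = 0.0293, in a range up to 0.964 over the alternatives). Ifit1 and Ifit3 fell by 0.97 and 1.25, but neither was called without control replicate 1 (adjusted p = 0.149 and 0.0957), control replicate 2 (0.0599 and 0.0502), DPCP replicate 2 (0.112 and 0.0774) or DPCP replicate 3 (0.117 and 0.0719). Genes of class I antigen presentation rose in 1 and fell in 2 of 10 cases (1 and 2 adjusted over the list alone; camera adjusted p = 0.48), with the regulator gene Nlrc5 at a log2 fold change of −0.77 ± 0.11.

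Of 15 dendritic and Langerhans cell genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.57). The Langerhans cell lectin gene Cd207 fell from 34.9 ± 3.49 to 10.4 ± 4.10 CPM (SD, n = 3) and Fscn1, an actin bundler of mature dendritic cells, rose from 13.8 ± 2.56 to 120 ± 12.03 CPM. The median of this list (−0.39) and its mean (−0.08) were negative, while fry gave it an upward direction (adjusted p = 0.90). Of 7 B and plasma cell genes, 1 rose and 1 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.48), and of the 3 eosinophil genes with enough counts, of 6 in the list, none was called by edgeR at an adjusted p under 0.05, over all genes or adjusted over the list alone. Camera gave the eosinophil list an upward direction (adjusted p = 0.79), while its median (−0.28) and mean (−0.07) were negative. Siglecf was at 1.94 ± 0.593 and 2.90 ± 0.694 CPM, and was called higher without control replicate 1 (log2 fold change 0.86, adjusted p = 0.0428).

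Of 26 genes of epidermal stress and hyperproliferation, 21 rose and 2 fell (21 and 2 adjusted over the list alone), with a median log2 fold change of 3.49 and a camera adjusted p of 1.8e-09 (adjusted p = 0.58 with an estimated correlation). Krt16 rose from 91.0 ± 23.0 to 4860 ± 686 CPM and Krt6a from 103 ± 19.3 to 5356 ± 1208 CPM (SD, n = 3), the latter uncertain because it shares sequence with Krt6b. Sprr2h, a cornified envelope precursor, rose by 4.58 ± 0.15 on the log2 scale, and the growth factor gene Ereg fell by 0.97 ± 0.08. Of 21 epidermal differentiation genes, 6 rose and 12 fell (6 and 12 adjusted over the list alone), with a camera adjusted p of 0.078. The list passed with DESeq2 statistics (0.000287), without a count filter (0.0218), without control replicate 2 (0.0136) and by fry (0.0436), and its adjusted p reached 0.806 with an estimated correlation. Flg2, a filaggrin family gene, fell from 2634 ± 357 to 336 ± 68.7 CPM, Krt10 from 5919 ± 1143 to 1020 ± 287 CPM and Lce1m from 1274 ± 191 to 126 ± 37.4 CPM (SD, n = 3), while the protease gene Klk7 rose by 1.62 ± 0.12.

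Basal keratinocyte genes rose in 5 and fell in 2 of 10 cases (6 and 2 adjusted over the list alone; camera adjusted p = 0.11). That list passed with DESeq2 statistics (0.00186), without a count filter (0.0431), without control replicate 3 (0.0474) and by fry (0.0164), and its adjusted p reached 0.806 with an estimated correlation. Krt14 rose from 4776 ± 396 to 17430 ± 1233 CPM (SD, n = 3) and was the gene with the most counts in DPCP replicates 1 and 3. Cell cycle genes rose in 24 of 25 cases, and in 25 of 25 adjusted over the list alone, with a median log2 fold change of 1.62 and a camera adjusted p of 3.5e-14 (adjusted p = 0.58 with an estimated correlation). Cdk1, the kinase that drives mitosis, rose from 20.1 ± 0.481 to 77.4 ± 5.38 CPM, Birc5 by 2.01 ± 0.11 and Tpx2 by 1.87 ± 0.09 on the log2 scale. Oxidative stress genes rose in 13 of 15 cases and fell in none (13 and 1 adjusted over the list alone), with a camera adjusted p of 1.8e-05 (adjusted p = 0.58 with an estimated correlation), led by the glutathione transferase gene Gsta4 (7.78 ± 0.867 to 344 ± 27.2 CPM).

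**Figure D2:**
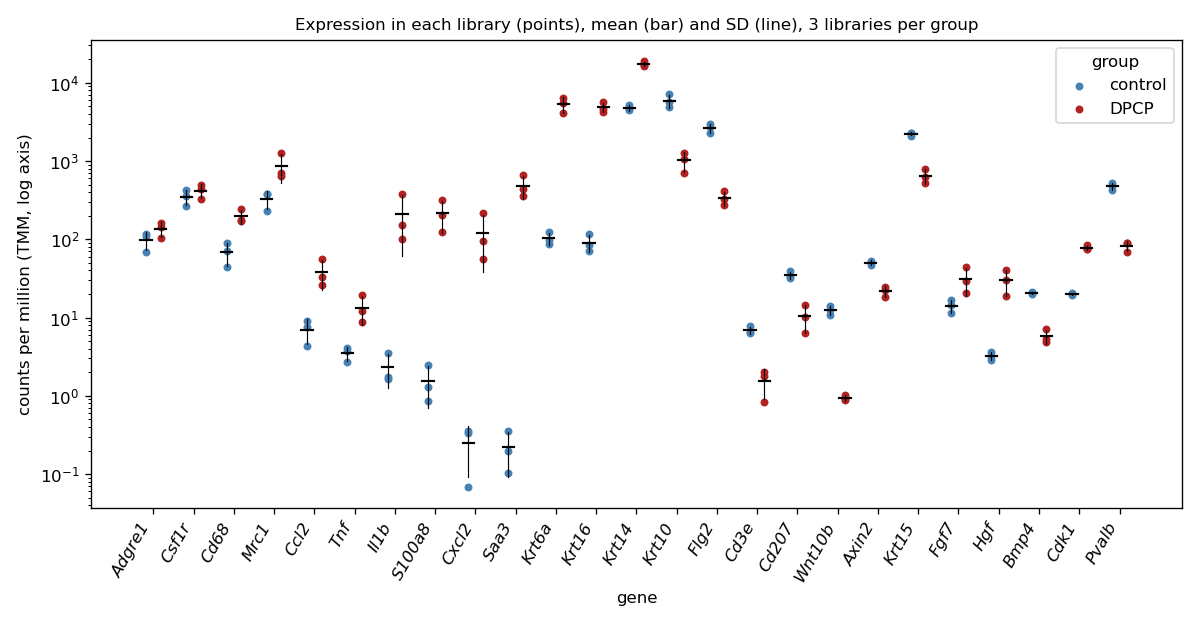
CPM (TMM, log axis) of 25 named genes in each of the 3 control and 3 DPCP libraries, with the mean (bar) and SD (line) of each group. Saa3 lay at 0.102 to 0.358 CPM in control and at 357 to 659 CPM in DPCP libraries, while the groups overlapped for Adgre1 and Csf1r.

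The tested genes of the hair follicle growth signalling list were lower or not called. Together they took 853 ± 29.5 CPM in control and 793 ± 21.1 CPM in DPCP libraries (SD, n = 3). Of 19 genes of this list, 10 fell and none rose, also adjusted over the list alone, with a median log2 fold change of −0.49 and a camera adjusted p of 0.019 (adjusted p = 0.65 with an estimated correlation). The log2 fold change of Wnt10b (ENSMUSG00000022996, chromosome 15, 98770712 to 98778150) was −3.72 ± 0.18 (SE). Those of Wnt7b and of Axin2, a target gene of Wnt signalling, were −1.54 ± 0.15 and −1.20 ± 0.12. Lef1 was at 1.03 ± 0.144 and 0.729 ± 0.0884 CPM (SD, n = 3; edgeR adjusted p = 0.184), and Shh had too few counts to be tested, with 2, 2 and 0 in the control and 0, 0 and 2 in the DPCP libraries. Among genes sharing no exon base, a setting chosen after seeing the data, the list's camera adjusted p was 0.109, with a median log2 fold change of −0.475. Its adjusted p ranged from 0.00186 to 0.649 over the alternatives. Wnt7b and Axin2 both share exon bases with an antisense gene.

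Of 15 hair follicle stem cell genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.047 (adjusted p = 0.65 with an estimated correlation). The adjusted p was 0.0561, 0.0541 and 0.142 without control replicate 2, DPCP replicate 1 and DPCP replicate 2. It was 0.058 with library totals, 0.052 with upper-quartile factors and 0.0825 among genes sharing no exon base, in a range of 0.0104 to 0.65 over the alternatives. Krt15, a keratin of bulge and basal cells, fell from 2225 ± 98.9 to 651 ± 141 CPM (SD, n = 3). The log2 fold changes of Lgr6 and Fgf18 were −1.41 ± 0.15 and −1.55 ± 0.15 (SE). Only 7 of the 28 hair shaft and inner root sheath genes had enough counts to be tested, of which 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.55). Krt28 fell from 4.43 ± 0.953 to 0.5003 ± 0.191 CPM and Krt32 from 3.80 ± 0.696 to 0.433 ± 0.154 CPM. By fry, which tests movement one way and not against other genes, this list passed (adjusted p = 0.011, against up to 0.983 over the alternatives).

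Secreted regulators of the hair cycle moved both ways, with 8 of 18 higher and 5 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.31). Hgf rose from 3.23 ± 0.381 to 29.8 ± 10.9 CPM and Fgf7, a keratinocyte growth factor, from 14.2 ± 2.62 to 31.1 ± 11.9 CPM (SD, n = 3). Spp1 (osteopontin) and Osm (oncostatin M) rose by 5.52 ± 0.58 and 4.54 ± 0.58 on the log2 scale (SE), or by 4.69 and 3.83 without DPCP replicate 2. Bmp4, which holds hair follicles at rest, fell from 20.7 ± 0.804 to 5.76 ± 1.13 CPM, and Igf1 was at 91.9 ± 10.2 and 95.6 ± 16.2 CPM (edgeR adjusted p = 0.761). Of 15 dermal papilla genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.96), among them Crabp1 higher by 1.97 ± 0.14 on the log2 scale. The log2 fold change of Rspo3, which amplifies Wnt signals, was −2.13 ± 0.31. Melanocyte genes rose in 2 and fell in 1 of 8 cases (2 and 1 adjusted over the list alone; camera adjusted p = 0.57).

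Genes of the sebaceous gland and lipid synthesis fell in 10 of 18 cases and rose in none (12 and 0 adjusted over the list alone), with a camera adjusted p of 0.0024 (adjusted p = 0.67 with an estimated correlation). Scd3, a desaturase of sebaceous glands, fell from 504 ± 126 to 53.2 ± 31.7 CPM and Dgat2 from 430 ± 67.3 to 235 ± 12.9 CPM (SD, n = 3). All 14 tested skeletal muscle genes fell, also adjusted over the list alone, with a median log2 fold change of −1.66 and a camera adjusted p of 1.1e-06 (adjusted p = 0.59 with an estimated correlation). Pvalb, the parvalbumin gene of fast fibres, fell from 476 ± 54.1 to 83.0 ± 12.1 CPM and the myoglobin gene Mb from 127 ± 1.96 to 28.7 ± 1.67 CPM (SD, n = 3). The 14 muscle genes together took 16630 ± 1920 CPM in control and 5661 ± 1820 CPM in DPCP libraries.

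Glial and nerve genes fell in 5 of 10 cases (6 adjusted over the list alone), with a camera adjusted p of 0.047 (adjusted p = 0.65 with an estimated correlation). The adjusted p was 0.144 without control replicate 2, 0.0683 without DPCP replicate 3 and 0.0599 with DESeq2 statistics. It was 0.058 with library totals, 0.0531 with upper-quartile factors and 0.0568 among genes sharing no exon base, in a range of 0.0152 to 0.649 over the alternatives. The log2 fold change of the myelin gene Mbp was −0.68 ± 0.13 (SE). Matrix remodelling and repair genes rose in 14 of 17 cases and fell in none (15 and 0 adjusted over the list alone), with a median of 1.91 and a camera adjusted p of 3.7e-06 (adjusted p = 0.59 with an estimated correlation). Tenascin C (Tnc) rose from 12.5 ± 2.85 to 1178 ± 409 CPM and the protease inhibitor gene Timp1 by 4.77 ± 0.32. Of 15 fibroblast and matrix genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.84), and of 15 adipocyte genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.36). None of 5 red blood cell genes was called by edgeR at an adjusted p under 0.05, or adjusted over the list alone (camera adjusted p = 0.61), with Hba-a1 at 117 ± 62.4 and 87.0 ± 29.5 CPM.

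The 16 list calls from camera, 11 upward and 5 downward, were made with a preset correlation of 0.01. With an estimated correlation 0 of the 35 lists passed (1 at an unadjusted p under 0.05, smallest adjusted p of 0.58), while fry called 11 upward and 7 downward.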

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

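Protein-coding genes alone, the omission of a ribosomal RNA gene and genes sharing no exon base were alternatives chosen after seeing the data, and the others were planned. No call of a named gene or list reversed its direction under any of them. With other normalizations, tests and count filters, 3517 to 4361 genes were higher and 3959 to 4858 lower. At an adjusted p under 0.01, 2740 genes were higher and 2657 lower, and with an absolute log2 fold change of at least 1, 1441 and 1665, fewer by construction. Among the 12271 tested genes sharing no exon base, 2708 were higher and 2891 lower, and 2 lists were lower, as the hair follicle growth signalling, hair follicle stem cell and glial lists lost their calls with fewer genes. Library totals alone and upper-quartile factors each left 3 lists lower, as the hair follicle stem cell and glial lists lost their calls, and the cause was not tested. The median log2 fold changes of these lists did not shrink. They were −0.417 and −0.377 for stem cell genes (main −0.348) and −0.588 and −0.542 for glial genes (main −0.511). The median of all tested genes moved the same way (−0.0878 and −0.0432, main −0.0136). Camera with an estimated correlation left 0 lists higher and 0 lower. Leaving out 1 library at a time gave 3492 to 4035 genes higher, 3430 to 4039 lower, 11 to 12 lists higher and 4 to 6 lower. With the replicate number as a block, 4260 genes were higher and 4241 lower, with 11 lists higher and 4 lower. The hair follicle stem cell list lost its call under the block (adjusted p = 0.0532), and Adgre1 and Csf1r were called higher (edgeR adjusted p = 0.00571 and 0.0371). Same-numbered libraries deviated together with correlations of 0.046, 0.027 and 0.11, so the numbers were not taken to pair the samples, and not every library correlated best with its own number. Over all alternatives, calls of named genes were lost 50 times and gained 5 times, and those of lists lost 33 times and gained 11 times. Tests on FPKM or TPM values were not run. Depth limits low genes, since 3 counts amount to up to 0.106 CPM.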

Other observations

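Families of related genes were compared by symbol stem after the data were seen, with Fisher's exact test. The 269 families held at least 8 tested genes each and were formed without regard to biotype. Of the 15013 genes used as background, 3782 were higher and 3652 lower. The test treats genes as independent, so its p-values do not measure the spread between samples. Nucleoporin genes (Nup) were higher in 17 of 20 cases (adjusted p of 8.38e-06) with a median log2 fold change of 0.60, proteasome regulatory subunit genes (Psmd) in 13 of 14 with a median of 0.38 (adjusted p of 1.88e-05), and mitochondrial ribosome genes (Mrpl) in 25 of 50 with a median of 0.31 (adjusted p of 0.00915). Kallikrein genes (Klk), which include proteases of the cornified layer, were higher in 8 of 10 cases (adjusted p of 0.0157). Klk6, named after its value was seen, was at 44.9 ± 10.6 CPM in control and 1746 ± 452 CPM in DPCP libraries (SD, n = 3). Cytochrome P450 genes (Cyp) were lower in 21 of 43 cases and higher in 10 (adjusted p of 0.0157), and Cyp2b19, also named after its value was seen, fell by 1.82 on the log2 scale.

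The tests on muscle and receptor genes below were chosen after the results were seen, while the matched-set test on zinc finger genes and the splits of the samples were set before theirs. The 14 skeletal muscle genes had a median log2 fold change of −1.66 (95% bootstrap interval over genes −1.83 to −1.39). The bootstrap intervals resample genes and leave out the spread between libraries. The muscle genes summed to 14800, 18630 and 16450 CPM in the control and 3863, 5618 and 7503 CPM in the DPCP libraries. Fibroblast, adipocyte and nerve genes had a median 1.43 higher than the muscle genes, at −0.23 (−0.39 to −0.08), with list medians of 0.06, −0.26 and −0.51. These list medians were known when the comparison was chosen, so the test adds no independent evidence. The values themselves argue against dilution by RNA of other cells, alike for all these tissues, as the whole cause. Induction of genes in the compared tissues could offset dilution and was not tested. After each library was centred on the mean of the muscle genes, 3 of the 14 still differed (Myh2 up by 0.88, Acta1 up by 0.51, Pvalb down by 0.85). The muscle genes thus did not all fall by the same factor. The bound of 3 genes was set after the gene values were known and was just met. It therefore cannot decide whether a smaller share of muscle tissue was the whole cause. A smaller share, alone or combined with altered muscle expression, may remain.

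The 7 genes of the CD3 complex and the epidermal γδ T cell receptor (Cd3d, Cd3e, Cd3g, Trdc, Trdv4, Tcrg-C1, Tcrg-V5) fell by 1.70 to 2.36 on the log2 scale, and all 11 Skint genes fell (median −2.38). Fibroblast, adipocyte and nerve genes had a median 1.91 higher than the receptor genes. The medians were −0.23 and −2.14 (95% bootstrap interval of the latter, over genes, −2.33 to −1.86). The 7 genes were picked after the results were seen, so part of that difference may come from the choice. The fixed T and NK cell list had a median of −0.35, with 2 genes higher and 7 lower of 19. No conclusion on dilution by RNA of other cells was drawn for the receptor genes. After centring on their mean 0 of the 7 receptor genes differed at an adjusted p under 0.05 (limma). The 95% intervals of 6 reached beyond 0.5, so a fall by the same factor was not shown. Genes lowered alike within each cell would also fall by the same factor. The test therefore cannot tell fewer receptor-bearing cells from less receptor RNA per cell, whatever the intervals. The requirement on the intervals was added after the count of 0 was seen.

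Zinc finger genes (Zfp) were lower in 150 of 361 cases and higher in 14, with a median log2 fold change of −0.33 that lay between −0.41 and −0.32 with other edgeR scalings. Of the 355 annotated as protein coding with a GC content, 149 were lower, against a mean of 89.5 and a highest of 121 in 10000 sets of other genes matched on expression, GC content and length. No set had as many, so the matched-set p was 0.0001, the smallest that 10000 sets can give. This argues against those properties as the whole cause, within the classes used for matching. Zfp had the smallest p of all the families in these same data, so a high count of lower genes was given in advance. The sets treat genes as independent, so the matched-set p does not measure the spread between samples. Reads lost between these related genes were not tested, and a biological difference may remain, as a hypothesis.

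The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 8417 genes, matched by 1 of the 10 splits (itself), and the highest of the others called 0 with edgeR (at most 327 at an unadjusted p under 0.05). The real split called 16 lists with camera, a number reached by 5 of the 10 splits, itself included, and the highest of the others called 25. Every other split mixed the groups unevenly, so part of the DPCP difference stayed between its sides and part within them. The calls of those splits, of genes or of lists, therefore set no chance level.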
